A study of Mus musculus with 4 samples.

How the data were processed

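The data were 4 2-colour microarrays of RNA from sorted cells of adult mouse colon. Each array carried RNA labelled Lgr5-GFP in 1 dye and RNA labelled CD24hi in the other. Per the labels, 300 ng of total RNA was labelled for each channel with a linear amplification kit. The arrays formed 2 replicates, each measured on a first array with Lgr5-GFP RNA in Cy3 and on a dye swap with that RNA in Cy5. Each replicate lay on its own slide, so slide and replicate cannot be told apart. The labels do not say whether the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

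Per the file headers, the arrays were scanned on an Agilent scanner and read with Feature Extraction 10.5.1.1. The deposited intensity values were the mean brightness of each spot and the median of its local background in green and red, with no normalization. Per the file headers, a further set of intensity values was background-subtracted with spatial detrending and dye-normalized by the same software. The deposited log10 ratio was that of red over green of those processed values. The deposited series table held a log2 ratio of red over green per array, as found by setting it against each array's own log10 ratio (r across probes of 0.977, 0.923, 0.950 and 0.986, with slopes of 3.22, 2.91, 3.21 and 3.30). Its column medians were -0.01, 0.03, -0.01 and -0.01, its swapped columns were not turned, and its normalization method is not given in the sources used here. Probe positions were those of the file annotation, build mm9.

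Background was corrected with normexp in limma 3.58.1 (R 4.3.3), with an offset of 50, and arrays were normalized by global loess with control spots at weight 0. Spots that the software marked as non-uniform or population outliers were left out, which removed 100, 32648, 222 and 163 of 43379 gene spots on the first array and dye swap of replicate 1 and the first array and dye swap of replicate 2. On the dye swap of replicate 1 this was 75.3% of spots, and 9420 of 14801 tested genes had no value there, so replicate 1 rested on its first array for them and was not dye-balanced. No spot was saturated. The removal of marked spots was not part of the design fixed in advance.

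One step departed from the design after its result was seen. With normexp fitted on all spots, as first planned, and marked spots then left out as above, limma called 0 of 14801 genes (5283 at an unadjusted p under 0.05). On the first array of replicate 2, 77 spots had a non-uniform local background of up to 398103. With them the fitted mean of the red background was -917.87, and without them it was 5.50. On the other arrays it was 4.97, 22.89 and 4.55. These spots were therefore left out before the fit, and every value is given under that choice unless stated. The 0 calls of the first version stand beside the counts of calls.

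Ratios were taken as log2 of RNA labelled Lgr5-GFP over RNA labelled CD24hi, so the sign of swapped arrays was turned. An array and its swap were averaged to 1 ratio per replicate, and limma tested the 2 ratios against 0 (2-sided, 1 residual degree of freedom, Benjamini-Hochberg over all genes tested, adjusted p under 0.05). The moderated fit had 4.69 prior degrees of freedom. Probes were kept if well above background on all 4 arrays in at least 1 of the populations, spots of a probe were averaged, and a gene was shown by its brightest kept probe. Of 4463 genes with 2 or more kept probes, 57 had probes called in opposite directions. Of the gene spots, 27041 took their gene name from a RefSeq table (assembly GRCm38.p6, used for names only), and 16338 kept the file's own name.

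A gene not well above background on any array of a population was given a bound on its mean fold over replicates, not on each replicate. The bound was the bright population's mean against the dim one's, per channel after loess and Aquantile scaling. The dim one's mean was that of, per array, the higher of the lowest signal well above background and the probe's own signal. The low spot count on the dye swap of replicate 1 leaves these channel levels partly open to dye bias.

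Gene lists for 29 cell types, pathways and processes, all of which are reported, were set before the data were examined, as were the tests and most alternatives. Lists of at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01 and with an estimated one. The latter test has 1 residual degree of freedom and could hardly call any list. Named genes were Lgr5, Cd24a, Reg4, Muc2, Kit and Atoh1, and the 12 largest ratios per direction among called genes with 1 direction on all arrays and signal above background in both populations. The 5 largest bounds per direction were added, with up to 4 called members and 2 further members per list. "All arrays" was applied over arrays with a value. The rule gave 173 genes, of which a part is described, and 1 member of a list is not reported here. Members named outside it are those a list left uncalled or turned the other way, chosen after their values were seen.

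The steps were tested on simulated arrays with known ratios, on 14801 genes. At a true log2 ratio of -2, -1, 1 and 2, 98%, 88%, 90% and 100% of 50 genes each were called with the right sign, and 16 of 14571 unchanged genes were called. A further list of genes was given a smaller ratio and is in neither count. The simulated arrays had no marked spots, the same noise on each, a spread drawn from the fit to these data, and few changed genes. The rates therefore do not describe arrays like the dye swap of replicate 1. An error that ranked probes with a missing brightness last was found and repaired, which left the total of calls at 7067.

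The alternatives were other background corrections and offsets, the software's processed signals, median centring, Aquantile scaling, the series table, other filters and probe summaries, and other variance models. A minimum fold, a stricter threshold, 1 dye orientation, each array or replicate left out, and rank-based camera were run too. Keeping marked spots and the replicate as a random block without a dye term were added after seeing the data. Keeping the non-uniform backgrounds in normexp was the background fit planned first, here run with marked spots left out. It became an alternative only after its result was seen. A pair of choices in comparing settings were also made after output was seen. The direction of an uncalled list was taken from its median, and lists under 5 members were left out of the search for arrays that stood apart. The number of arrays limits the precision of every value.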

Results

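Gene expression was compared between sorted epithelial populations of the mouse colon. In the mice, GFP is driven from the locus of Lgr5, a receptor of crypt base stem cells, and the other population was sorted with an antibody to CD24, a surface protein, at its high level, which the design describes as a way to obtain a subset of goblet cells. The comparison asks which genes differ between the Lgr5-GFP and the CD24hi cells. RNA of both populations was hybridised together to 4 arrays, as 2 replicates of a first array and a dye swap (n = 2). Median spot signals of the RNA labelled Lgr5-GFP were 109, 4377, 94.2 and 164 on the first array and dye swap of replicate 1 and the first array and dye swap of replicate 2. Those of the RNA labelled CD24hi were 197, 1358, 169 and 110. The dye swap of replicate 1 stood apart in signal, and 75.3% of its spots were left out as marked outliers. Across genes, which are not independent replicates, the arrays turned to 1 direction correlated at r of 0.724 to 0.958, and the replicates at 0.909.

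The sort markers ran against the labels. Lgr5 (probe at chromosome 10, 114888847 to 114888906, mm9) was 10.6-fold lower in the RNA labelled Lgr5-GFP than in the RNA labelled CD24hi, at a log2 ratio of -3.41 ± 0.29 (SD, n = 2 replicates; limma, adjusted p = 4.60e-04). Cd24a, which encodes CD24 (chromosome 10, 43303706 to 43303765), was 4.35-fold higher in the RNA labelled Lgr5-GFP, at 2.12 ± 0.30 (limma, adjusted p = 5.93e-04). Both held their direction on every array with a value, which was 3 arrays for Lgr5 and 4 for Cd24a. In the RNA labelled Lgr5-GFP, Lgr5 was well above background on 2 of those 3 arrays only, and its ratio was -3.02 with no background subtraction, -4.80 with the processed signals and -2.69 with marked spots kept. Each direction here is that of the labels, and with the sign turned every higher becomes lower. Muc2, the main secreted mucin of goblet cells (chromosome 7, 148940000 to 148940059), was 13.5-fold higher in the RNA labelled Lgr5-GFP (3.76 ± 0.58). Atoh1, the transcription factor that specifies secretory cells, was higher at 2.57 ± 0.06, and Kit, a receptor tyrosine kinase, at 1.74 ± 0.46. The log2 ratio of Reg4, a lectin of deep crypt secretory cells, was 2.08 ± 1.69 (limma, adjusted p = 0.0207), with 0.88 in replicate 1 and 3.28 in replicate 2. Its call was lost without background subtraction (limma, adjusted p = 0.0590) and without the filter on dim probes (0.0593), and over all alternatives the adjusted p ran from 6.55e-06 to 0.0976.

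**Figure D1:**
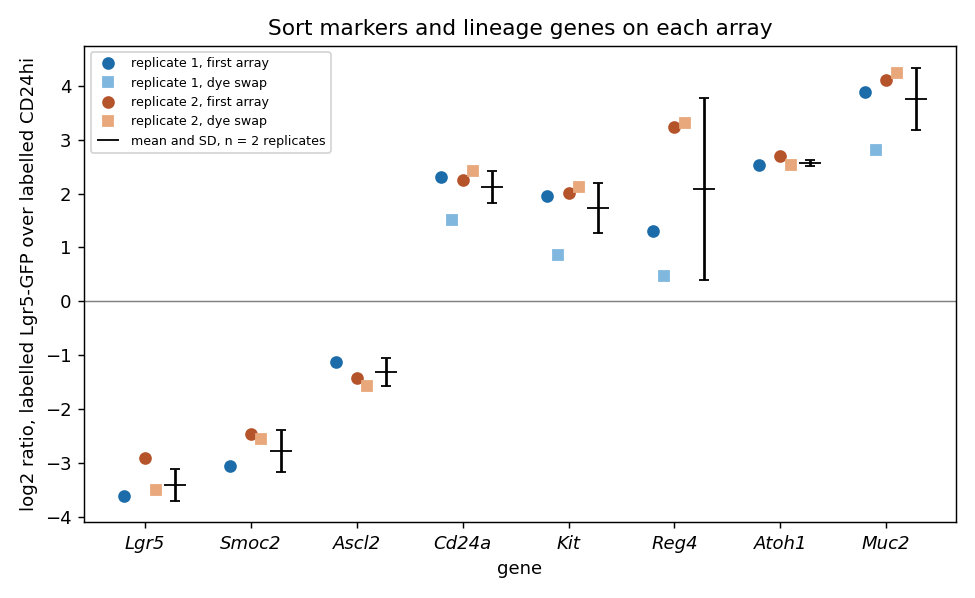
Log2 ratio of RNA labelled Lgr5-GFP over RNA labelled CD24hi (vertical axis) for 8 genes on each array, with circles for first arrays, squares for dye swaps, and black marks for the mean and SD of 2 replicates. Lgr5 (-3.41) lies below 0 and Cd24a (2.12) above 0, against the labels, on every array with a value.

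Limma called 7067 of 14801 tested genes (47.7%), of which 3247 were higher in the RNA labelled Lgr5-GFP and 3820 in the RNA labelled CD24hi. The non-uniform backgrounds of 1 array were left out before background correction, and this was decided after the background fit planned first had called 0 genes by limma (5283 at an unadjusted p under 0.05, smallest adjusted p = 0.0802). Marked spots were left out in that run too, which the design had not fixed. Other treatments of the signal set in advance, with marked spots left out as well, called 6386 genes with no background subtraction, 7241 with the scanner software's processed signals and 7065 with the series table. With each array only centred on its median, the split of calls was 2217 higher and 5402 lower, and the median of all genes moved from -0.07 to -0.25 (-0.17 with the series table). Without the first array of replicate 1, which left that replicate to its outlier-rich dye swap, 983 of 6022 genes were called. Marked spots kept, with the non-uniform backgrounds left out, gave 3731 calls, and no setting kept both. Both replicates differed at least 2-fold in the same direction for 1783 genes, 889 higher and 894 lower in the RNA labelled Lgr5-GFP. That count was 3170 with the processed signals, 3142 with the series table, 713 with the non-uniform backgrounds kept, 398 without the first array of replicate 1 and 396 on the dye swaps alone.

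**Figure D2:**
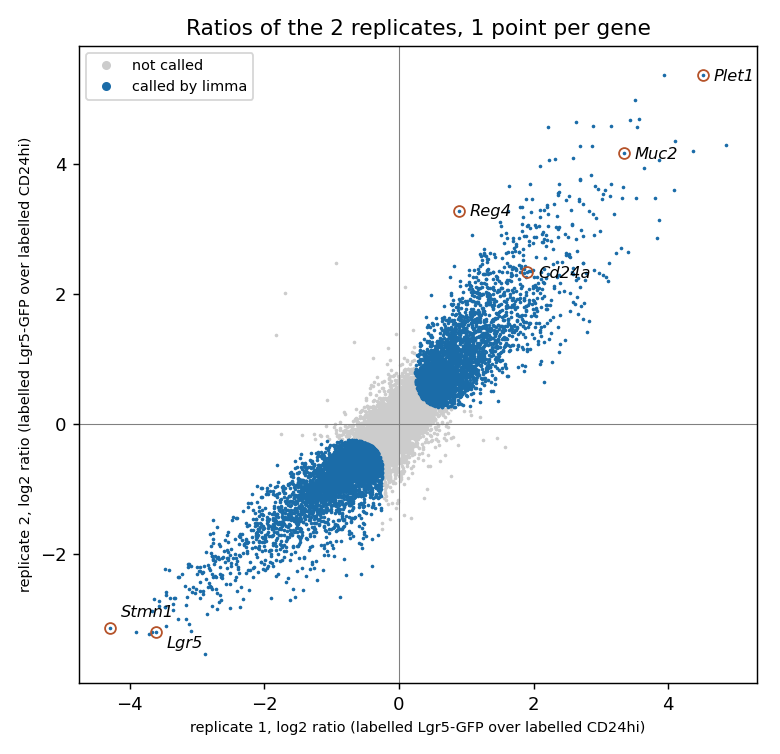
Log2 ratio of RNA labelled Lgr5-GFP over RNA labelled CD24hi in replicate 1 (horizontal axis) and replicate 2 (vertical axis), 1 point per gene, with genes called by limma in blue and not called in grey. Ratios of the replicates correlated at r = 0.909 across 14801 genes.

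The largest ratio toward the RNA labelled Lgr5-GFP was that of Plet1, a surface protein, at 4.94 ± 0.61 (30.7-fold, n = 2). Ccl6, a chemokine, had 4.65 ± 1.02, Ceacam12, a member of the carcinoembryonic antigen family, 4.58 ± 0.40, and Palmd 4.28 ± 0.12. Ccn3, a matricellular protein, had 4.25, Nupr1, a stress-induced regulator, 4.23, Clps, the colipase gene, 4.13, and Retnlb, a secreted product of goblet cells, 4.05. Their order depends on the dye swap of replicate 1, where Ceacam12, Palmd and Clps had no value. Without that array the log2 ratio of Plet1 was 5.26, the log2 ratio of Ccn3 5.25 and the log2 ratio of Ccl6 5.23. Toward the RNA labelled CD24hi the largest was Stmn1, a microtubule-destabilising protein of dividing cells, at -3.72 ± 0.81 (13.2-fold). Rgcc, a cell cycle regulator, had -3.56 ± 0.50, Mpzl2, an adhesion molecule, -3.47 ± 0.34, and Acot1, an acyl-CoA thioesterase, -3.44 ± 0.33. Kcnq1, a potassium channel, had -3.29, Gsta3, a glutathione transferase, -3.27, Birc5, which encodes survivin, -3.18, and Edn1, which encodes endothelin 1, -3.14. All of these genes were called by limma, at adjusted p of 7.02e-04 (Ccn3) or below. Lamb1, a laminin chain, was not well above background in the RNA labelled CD24hi and was at least 5.17-fold higher in the other, and Ptgs1, a cyclooxygenase, at least 3.65-fold. Rad51b, a DNA repair gene, was not well above background in the RNA labelled Lgr5-GFP and was at least 2.83-fold lower there. Il33, an alarmin, was at least 2.23-fold lower there. These bounds hold for the mean of the replicates, and for each gene 1 replicate lay below its bound. Log2 ratios in replicates 1 and 2 were 2.65 and 2.25 for Lamb1, 2.47 and 1.30 for Ptgs1, -1.64 and -1.47 for Rad51b, and -1.11 and -1.59 for Il33. The bounds are also those of the background correction used. Over all alternatives the log2 ratio of Lamb1 ran from 1.78 to 6.29, that of Ptgs1 from 1.29 to 6.10, that of Rad51b from -3.71 to -1.13 and that of Il33 from -3.97 to -0.94. Brca2, also of DNA repair, was on average 3.34-fold lower in the RNA labelled Lgr5-GFP (log2 ratios of -1.88 and -1.60 in replicates 1 and 2). Its bound equalled this measured fold, so it adds no lower limit. With no filter on dim probes another probe stood for it, and the log2 ratio of Brca2 was no longer called (-0.33, limma, adjusted p = 0.0864, over all alternatives 4.24e-05 to 0.0888).

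Goblet cell and secretory genes were higher in the RNA labelled Lgr5-GFP, the population whose sort markers ran against its label. Of 31 goblet cell markers, 26 rose and 1 fell there (26 and 2 adjusted over the list alone), with a median log2 ratio of 2.44 (limma's camera, adjusted p = 9.42e-11, and adjusted p = 0.598 with an estimated correlation). Agr2, a disulfide isomerase needed for mucin assembly, had 3.34 ± 0.69, Spink4 3.34 ± 1.08 and Klk1, a kallikrein, 3.05 ± 0.18. Among members not called, Tff3, the goblet cell trefoil peptide, had -0.95, Zg16 0.30, Tff1 0.14 and Fcgbp 0.10, and Nxpe4 fell (-1.70). Of 24 mucin glycosylation genes, 22 rose and 1 fell (22 and 1 adjusted over the list alone), with a median of 1.57 (camera in limma, adjusted p = 3.04e-09, and 0.598 with an estimated correlation). Fut2, a fucosyltransferase, had 2.74 ± 0.16 and B3gnt3 2.33 ± 0.06, and the membrane mucin Muc3 fell (-1.95 ± 0.25). Of 45 genes of the endoplasmic reticulum and secretory pathway, 38 rose and 1 fell (39 and 1 adjusted over the list alone; median 0.92; limma, adjusted p = 2.18e-11, and 0.598 with an estimated correlation). They included Kdelr3, a retention receptor (3.15 ± 1.29), Ern2, a stress sensor of mucous cells (2.57 ± 1.08), and Edem2 (2.08 ± 0.08), and Canx, which encodes calnexin, fell (-0.86). Kdelr3 (1.41) and Ern2 (0.99) were lowest on the dye swap of replicate 1, where Edem2 had no value, so these means and SDs are not alike. Of 17 secretory lineage transcription factors, 10 rose and 1 fell, also adjusted over the list alone (median 0.69; limma, adjusted p = 3.59e-04, and 0.598 with an estimated correlation), among them Spdef (2.82 ± 1.24), Gfi1 (2.49 ± 0.81) and Xbp1 (2.12 ± 0.48), and Sox4 fell (-1.20). That median was 1.44 without the first array of replicate 1, and 0.41 to 1.52 over all alternatives. Of the goblet cell markers 11, and of the transcription factors 12, were also in another list.

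Markers of other mature cell types lay on the same side. Of 18 markers of Paneth and deep crypt secretory cells, 13 rose and 2 fell in the RNA labelled Lgr5-GFP, whose sort markers ran against its label (14 and 3 adjusted over the list alone; median 1.85; limma, adjusted p = 7.58e-06, and 0.598 with an estimated correlation). Copz2 had 3.51 ± 0.03, Mmp7, a metalloproteinase, 2.46 ± 0.05 and Egf, the epidermal growth factor, 2.23 ± 0.54. The defensin Defa3 (-0.64 ± 0.44) fell, as did Wnt3, a Wnt ligand (at least 1.29-fold, not well above background there), and the defensin Defa20 (0.42) and the Notch ligand Dll1 (-0.49) were not called. Cd24a and Reg4 were among 10 members also in another list. Of 27 enteroendocrine markers, 14 rose and 1 fell, also adjusted over the list alone (median 0.84; limma, adjusted p = 3.14e-05, and 0.598 with an estimated correlation). The granule proteins Chgb (3.87 ± 1.02) and Chga (3.64 ± 1.43), the serotonin synthesis enzyme Tph1 (3.03 ± 1.33) and the hormones Sst (2.96 ± 0.69) and Sct (2.81 ± 0.11) were the largest. Ddc, also of serotonin synthesis, fell (-1.13 ± 0.02). The hormones Gcg (-1.69 in replicate 1 and 2.01 in replicate 2), Pyy (-0.94 and 2.48), Insl5 (-1.83 and 1.37) and Cck (-0.67 and 1.26) differed in sign between replicates and were not called. Of 20 tuft cell markers, 17 rose and 1 fell, also adjusted over the list alone (median 1.14; limma, adjusted p = 4.07e-07, and 0.598 with an estimated correlation). Dclk1, a kinase that marks tuft cells, had 2.28 ± 0.37, and Trpm5, their cation channel, 1.97 ± 0.45, while Hpgds, a prostaglandin synthase not above background on every array in the RNA labelled Lgr5-GFP, fell (-0.93). Of 27 absorptive colonocyte markers, 14 rose and 2 fell (15 and 2 adjusted over the list alone; median 0.47; limma, adjusted p = 7.38e-04, and 0.598 with an estimated correlation). The peptide gene Guca2a had 3.05 ± 0.33 and the sodium channel subunit Scnn1a 2.54 ± 0.40. In the RNA labelled CD24hi, Dclk1 was well above background on 1 of 3 arrays, and with the processed signals the log2 ratio of Dclk1 was 4.62. Over all alternatives the medians ran from 0.86 to 2.19 for tuft cell markers (2.19 with the processed signals), from 0.53 to 1.79 for enteroendocrine markers and from 0.34 to 0.70 for absorptive colonocyte markers.

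Stem cell, Wnt, Notch and cell cycle genes were higher in the RNA labelled CD24hi, the population in which Lgr5 itself was higher. Of 30 intestinal stem cell markers, 20 fell and 2 rose in the RNA labelled Lgr5-GFP, also adjusted over the list alone (median -1.09; limma, adjusted p = 8.60e-05, and 0.598 with an estimated correlation). Smoc2, a matricellular stem cell marker, had -2.78 ± 0.39, Cdca7 -2.43 ± 0.11, Rnf43, a ubiquitin ligase that limits Wnt signalling, -2.09 ± 0.06, and Ascl2, a stem cell transcription factor, -1.31 ± 0.25. Soat1 (1.74) and Tnfrsf19 (1.06) rose, and among members not called were Sox9 (-0.01), Bmi1 (-0.02) and Ephb2 (0.14). Of 19 Wnt target genes, 11 fell and 2 rose (11 and 3 adjusted over the list alone; median -1.03; limma, adjusted p = 0.0155, and 0.598 with an estimated correlation), among them Myc at -2.39 ± 0.05. Wif1, a secreted Wnt inhibitor, rose (1.54 ± 0.81, and 1.06 to 3.78 over all alternatives), but was above background on 1 of 3 arrays in the RNA labelled CD24hi. Of these, 12 were also in another list, and without the first array of replicate 1 the call was lost (limma, adjusted p = 0.162, over all alternatives 0.00161 to 0.598) and the stem cell median was -0.58. Over all alternatives the medians ran from -1.46 to -0.58 for stem cell markers and from -1.32 to -0.36 for Wnt target genes. Of 10 Notch receptors and targets, 7 fell and 0 rose, also adjusted over the list alone (median -0.67; limma, adjusted p = 0.00981, and 0.598 with an estimated correlation). Hes1, the main transcriptional target, had -1.51 ± 0.09. This call was lost when genes had to be above background in both populations (limma, adjusted p = 0.191, over all alternatives 0.00282 to 0.598), where the median was -0.25. It was -1.79 with the processed signals. Of 34 cell cycle genes, 33 fell and 0 rose (34 and 0 adjusted over the list alone), with a median of -2.16 (limma's camera, adjusted p = 3.52e-14, and 0.598 with an estimated correlation). Mki67, the proliferation antigen, had -3.03 ± 0.62, and the replication helicase subunits Mcm6 and Mcm4 had -2.98 ± 0.27 and -2.89 ± 0.06.

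**Figure D3:**
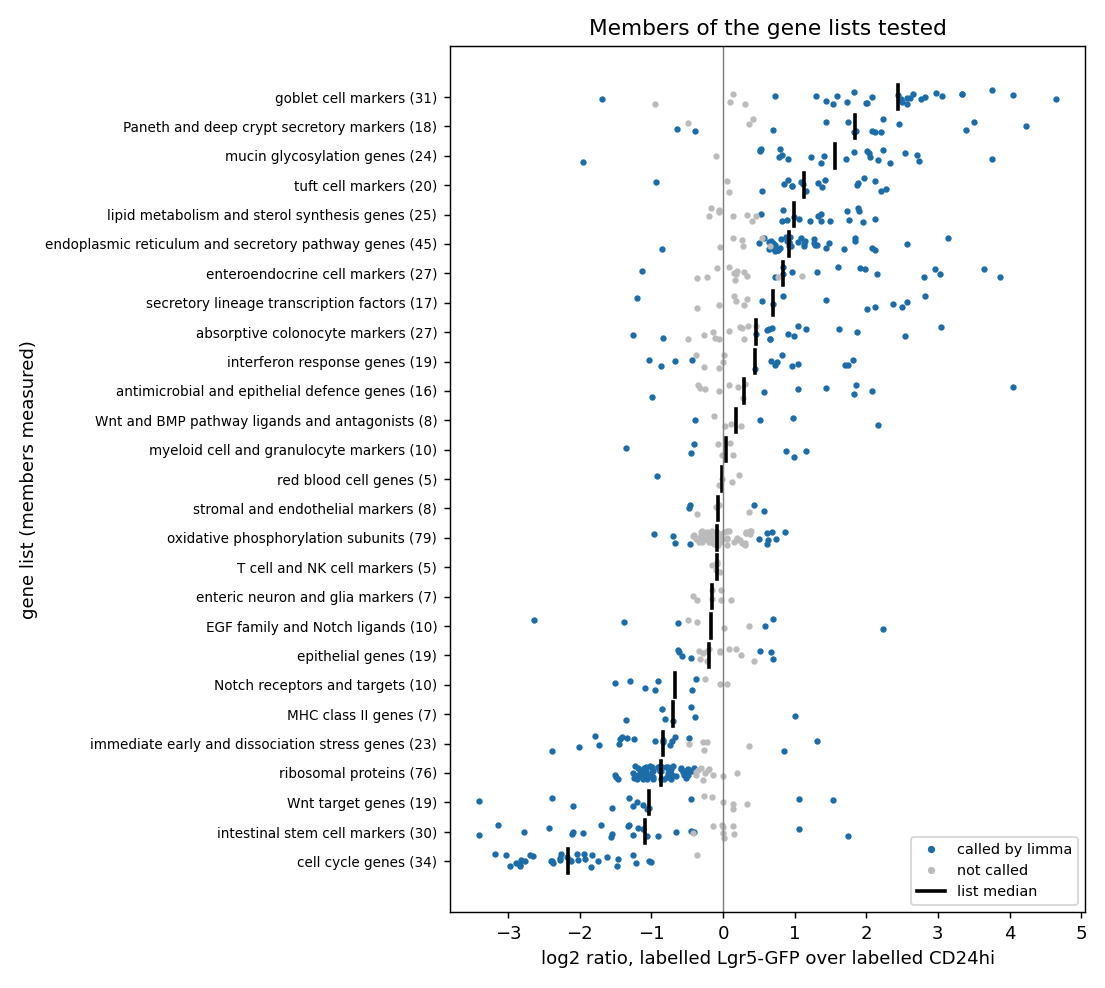
Log2 ratio of RNA labelled Lgr5-GFP over RNA labelled CD24hi (horizontal axis) of each measured member of the 27 lists tested (vertical axis, members in brackets), with members called by limma in blue, not called in grey, and a bar at the list median. Medians ran from -2.16 for cell cycle genes to 2.44 for goblet cell markers.

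Ribosomal protein and immediate early genes also lay toward the RNA labelled CD24hi. Of 76 ribosomal protein genes, 65 fell and 0 rose in the RNA labelled Lgr5-GFP (67 and 0 adjusted over the list alone; median -0.86; limma, adjusted p = 1.36e-13, and 0.598 with an estimated correlation). Rps9 had -1.50 and Rps19 -1.47 ± 0.07, and the list's direction was the same under each scaling tried, with a median of -1.14 to -0.24 over all alternatives. Of 23 immediate early and dissociation stress genes, 16 fell and 2 rose (16 and 3 adjusted over the list alone; median -0.84; limma, adjusted p = 1.53e-04, and 0.598 with an estimated correlation). The transcription factors Egr2 (-2.02 ± 0.17) and Egr1 (-1.73 ± 0.02) and the heat shock gene Hspa1a (-1.43 ± 0.34) were among them, and Klf2 (1.31) and Gadd45g (0.85) rose.

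Markers of cells outside the epithelium gave no list call, but fewer of their listed members were measured than of goblet cell markers (31 of 32). Measured were 5 of 22 T and NK cell, 4 of 18 B cell and 10 of 27 myeloid markers. For stromal and endothelial markers it was 8 of 22, for enteric neuron and glia markers 7 of 15 and for red blood cell genes 5 of 13. None of 5 T and NK cell markers was called, also adjusted over the list alone (median -0.09; limma, adjusted p = 0.840). Of 7 enteric neuron and glia markers 0 were called, also adjusted over the list alone (median -0.15; limma, adjusted p = 0.728). Of 10 myeloid markers, 3 rose and 3 fell in the RNA labelled Lgr5-GFP, also adjusted over the list alone (median 0.04; limma, adjusted p = 0.660). Alox5ap (1.16), a leukotriene synthesis gene, and Cd74 (-1.36), the MHC class II invariant chain, were each in another list too. Of 8 stromal and endothelial markers, 2 rose and 2 fell (3 and 3 adjusted over the list alone), with a median of -0.07, a mean of -0.01 and a camera direction above 0 (limma, adjusted p = 0.943). Of 5 red blood cell genes, 0 rose and 1 fell (Eraf, at least 1.75-fold lower and not well above background there), also adjusted over the list alone (median -0.01; limma, adjusted p = 0.943). Over all alternatives the log2 ratio of Eraf ran from -3.42 to -0.59. The B cell list had 4 measured members and was not tested, and Pou2af1 (-0.51, above background on 1 of 3 arrays in the RNA labelled Lgr5-GFP) alone was called, with 0 calls adjusted over the list alone. The log2 ratio of Pou2af1 ran from -1.59 to -0.29 over all alternatives (limma, adjusted p = 0.00211 to 0.195), so its call was lost in part of them. Of 19 epithelial genes, 3 rose and 4 fell (2 and 4 adjusted over the list alone; median -0.20; limma, adjusted p = 0.943). Epcam, the epithelial adhesion molecule, had -0.28 and was not called. In all, limma's camera called 16 of 27 lists at the preset correlation, 10 toward the RNA labelled Lgr5-GFP and 6 toward the RNA labelled CD24hi, and 0 with an estimated correlation. The latter test rests on 1 residual degree of freedom and could hardly call any list. Its 0.598 therefore does not show that correlation between genes removed the calls. The stem cell list had an estimated correlation of -0.03, below the preset 0.01, and still had 0.598. Over the called lists the estimates ran from -0.05 (antimicrobial and epithelial defence) to 0.75 (endoplasmic reticulum and secretory pathway). Goblet cell markers had 0.54 and cell cycle genes 0.48. Where the true correlation exceeds 0.01, the adjusted p at the preset is too small. The estimates also rest on 1 residual degree of freedom.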

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

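The tests of exchanged dye labels, of a cross-hybridising probe, of outlier-marked spots and of a different RNA pair were chosen only after the result was seen. The tests of added signal and of the ribosomal protein genes were set down before their results.

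The sort markers ran against the labels, with Lgr5 at -3.41 and Cd24a at 2.12 in the log2 ratio of RNA labelled Lgr5-GFP over RNA labelled CD24hi. Exchanged labels on a single array were argued against by the correlations between turned arrays, of which the lowest was 0.724. A cross-hybridising Lgr5 probe was argued against by the stem cell list without Lgr5, whose median over 29 genes was -1.06 (95% bootstrap interval -1.33 to -0.40). Dye labels exchanged on all 4 arrays stay open. The goblet cell median lay above the stem cell median by at least 1.46 on each array, but this cannot decide. Exchanged labels and a real difference between the sorted populations in the direction of the labels would both give it. The sort markers argue against that real difference, for these genes. Cells sorted for GFP from the Lgr5 locus should hold more Lgr5, and CD24hi cells more Cd24a, and both ran the other way. Whether the sorted samples rather than the dyes were exchanged was not tested.

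The dye swap of replicate 1 stood far from the other 3 arrays in the share of spots marked as outliers, 75.3% against 0.231% to 0.512%, and in median signal, 4377 and 1358 for RNA labelled Lgr5-GFP and CD24hi against at most 164 and 197. An exchanged RNA pair was argued against by its correlations with the other arrays, the lowest being 0.724. A different pair from the same populations stays open. Such a pair could correlate as well, as the first array of replicate 1 did with those of replicate 2 (0.936 and 0.925). The marked spots as the whole cause were argued against by its unmarked ones. Their slope on the other arrays was 0.514, which was 0.457 of that of the dye swap of replicate 2 (1.12) over 5372 genes. The latter slope was taken on a mean that held the dye swap of replicate 1, so this share may overstate the gap. Signal added to nearly every spot may account for it. With the marked spots of that array kept, the slope rose from 0.104 in the dimmest of 3 equal bins of genes to 0.512 in the brightest. The difference was 0.408 (0.394 to 0.422 at 2 standard errors, 14774 genes). That interval takes genes as independent, which they are not. Brightness was not separated from the marking of spots, and the unmarked spots alone had 0.514. A control chosen later took the slopes on the 2 first arrays only. There the difference was 0.0352 for the dye swap of replicate 2 and 0.402 for that of replicate 1. No biological explanation was tested, as both arrays of a replicate are read as the same RNA.

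Ribosomal protein genes lay together toward the RNA labelled CD24hi, whose sort markers ran against its label, with a list median of -0.86 over 76 genes. A bias with spot brightness was argued against, as the median lay at percentile 0 of 10000 random lists matched on brightness, whose central 95% ran from -0.31 to 0.08. The choice of scaling as the whole cause was argued against by the median nearest 0 over 6 other corrections and normalizations, -0.65, the lowest being -1.14. In those 6 the median of all genes lay between -0.25 and -0.05, so they cannot show a scaling error that they share. With the non-uniform backgrounds kept, which was not among those 6, the list of ribosomal proteins had -0.24, so part of its size could depend on that choice. Signal shared with ribosomal pseudogenes or paralogs, and a difference between the sorted populations, were not tested and stay open.

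Of 101 measures with 4 values, 18 had an array far from the others by Dixon's criterion, which chance gives in about 1 of 20, and 16 of the 18 came from the dye swap of replicate 1. On that array the mucin glycosylation median was 0.54 (1.71 to 1.74 on the others) and the lipid and sterol median 0.26 (at most 1.05 on the others). Its log2 ratios toward 0 were Kit 0.86, Plet1 3.87, Ccl6 2.78, Ccn3 1.5, C1galt1c1 1.82, Gcnt3 1.46, Ihh 0.34, Gfi1 1.05, Xbp1 0.99 and Scnn1a 1.46, each below the other arrays. Uqcrc2, a complex III subunit, was at -1.41 there and between -0.49 and -0.37 elsewhere. The cell cycle median was -2.69 on the first array of replicate 1 (-1.97 to -1.85 on the others), and Mcm6 was -2.49 on the first array of replicate 2 (-3.18 to -3.08 on the others).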

How the results depend on the processing

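The settings that keep marked spots or take the replicate as a random block without a dye term were chosen after seeing the data. Keeping non-uniform backgrounds in the background fit was planned first, and became an alternative only after its result was seen. The fit with a dye effect and a random replicate block was not run, since that model could not be fitted to 4 arrays. With the replicate block and no dye effect, 8248 genes were called. Over all alternatives, ratios of named genes kept their direction and, where tested, side of the threshold in 3055 cases, lost the call in 274, gained it in 30 and turned sign in 4. Those of lists did so in 500, 20, 8 and 15. The 3055 cases include those with a replicate left out, where no test was run. Such a ratio was counted as kept if within the SD of the replicates, which always holds, unless a called gene turned sign. Lgr5 ranged from -4.80 to -2.69 and Cd24a from 1.91 to 2.57. Signal over background limits dim genes: on the first array of replicate 2, 41.2% of spots were above background in the RNA labelled Lgr5-GFP.

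Counts of called genes, with those higher and lower in the RNA labelled Lgr5-GFP, were 2046 (1008 and 1038) against a fold of 1.5 and 4216 (2026 and 2190) at an adjusted p under 0.01 in limma, by construction of those tests. They were 969 (493 and 476) on the 2 dye swaps alone, where 6021 genes were measured, 396 were 2-fold apart and replicates correlated at 0.733, and 3731 (1435 and 2296) with marked spots kept. With non-uniform backgrounds kept in the normexp fit, limma called 0 (0 and 0; 5283 at an unadjusted p under 0.05), 713 were 2-fold apart, and Lgr5 (-2.71, adjusted p = 0.0857) and Cd24a (2.57, 0.0811) were not called. These lost calls followed from the fitted background of 1 array. Over the other settings in which each was tested, Lgr5 and Cd24a were called in limma, with adjusted p down to 1.07e-05 and 2.46e-06. Lgr5 had no value on the dye swaps alone, without the first array of replicate 1 or with both populations above background. It was marked on the dye swap of replicate 1, and was above background on 2 of 3 arrays in the RNA labelled Lgr5-GFP. Genes 2-fold apart numbered 3170 with the processed signals and 3142 with the series table; the cause was not tested. With an array left out, calls ran from 983 to 8540, those higher from 500 to 3990 and those lower from 483 to 4550. The 2-fold counts then ran from 398 to 2164 and the correlation of replicates from 0.730 to 0.940. Counts of 2604 without replicate 1 and 2410 without replicate 2 are not comparable, as only the remaining replicate had to be 2-fold apart. The lowest came without the first array of replicate 1 (6022 genes measured) and the highest counts of calls without its dye swap. Camera in limma called 0 lists with an estimated correlation, a test that could hardly call any.

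Lists and genes that turned sign were never past the threshold in the alternative, and the cause was not tested. The list of myeloid cell and granulocyte markers had -0.050 with processed signals, -0.14 with median centring, -0.020 with the series table and -0.016 with a dye effect. Median centring also gave the list of Wnt and BMP pathway ligands and antagonists -0.0026 and the log2 ratio of Hba-a1 -0.035. Without the dim filter, the list of stromal and endothelial markers had 0.0026, the list of enteric neuron and glia markers 0.0019 and the list of red blood cell genes 0.051. With an array left out the last ran from -0.011 to 0.017 (without the first array of replicate 2), and it had 0.0075 with marked spots and 0.0015 with non-uniform backgrounds. With both populations above background, the list of EGF family and Notch ligands had 0.013 and that of stromal and endothelial markers 0.13, and on the dye swaps the log2 ratio of Cr2 was 0.042. Non-uniform backgrounds gave the list of epithelial genes 0.13, the list of oxidative phosphorylation subunits 0.022, the log2 ratio of Notch2 0.013 and the log2 ratio of Krt8 0.45.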

Other observations

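Of 7 further lists, 2 were called between the sorted RNAs, whose sort markers ran against the labels. Of 25 genes of lipid metabolism and sterol synthesis, 17 rose and 0 fell in the RNA labelled Lgr5-GFP (18 and 0 adjusted over the list alone; median 0.99; limma, adjusted p = 3.83e-07, and 0.598 with an estimated correlation). Cyp51, which demethylates lanosterol, had 2.12 ± 0.08 (SD, n = 2) and Msmo1, of the same pathway, 1.89 ± 0.43. Without the first array of replicate 1 the list of lipid metabolism and sterol synthesis genes had a median of 0.61, and over all alternatives 0.57 to 1.13. Of 16 antimicrobial and epithelial defence genes, 7 rose and 1 fell, also adjusted over the list alone (median 0.29; limma, adjusted p = 0.0258, and 0.598 with an estimated correlation), with Ang4, an antimicrobial ribonuclease, at 1.84 ± 0.12. With a dye effect in the fit, the list of antimicrobial and epithelial defence genes was not called (limma, adjusted p = 0.0557, over all alternatives 0.00135 to 0.598), and 7 of its members were also in another list. Reg1, not above background on every array in the RNA labelled Lgr5-GFP, fell (-0.99). The list's median ran from 0.06 with median centring to 0.76 on the dye swaps alone.

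The interferon response genes had no list call, with 10 of 19 rising and 4 falling in the RNA labelled Lgr5-GFP (10 and 5 adjusted over the list alone; median 0.44; limma, adjusted p = 0.141). Oas2, an antiviral synthetase, was higher but above background on 2 of 4 arrays in the RNA labelled CD24hi (log2 ratio of Oas2 1.21 to 4.25 over all alternatives). Cxcl10, a chemokine, was lower but above background on 1 of 3 arrays in the RNA labelled Lgr5-GFP (log2 ratio of Cxcl10 -2.65 to -0.75). The list of interferon response genes was called with the series table (limma, adjusted p = 0.0402) and without the dim filter (0.0290), and over all alternatives its adjusted p ran from 0.0290 to 0.768 and its median from 0.18 to 0.53. Of 7 MHC class II genes, 6 fell and 1 rose, also adjusted over the list alone (median -0.69; limma, adjusted p = 0.0849). Cd74 had -1.36 ± 0.07 and H2-DMb1, of peptide loading, 1.01 ± 0.01. The list of MHC class II genes was called with processed signals (limma, adjusted p = 0.0417, over all alternatives 0.0295 to 0.598), and its median ran from -1.33 to -0.44. Of 10 ligands of the EGF and Notch families, 3 rose and 3 fell (4 and 5 adjusted over the list alone; median -0.17; limma, adjusted p = 0.943), with Hbegf at -2.65 ± 0.01 and Areg at -1.38 ± 0.11. Of 8 Wnt and BMP ligands and antagonists, 3 rose and 1 fell, also adjusted over the list alone (median 0.18; limma, adjusted p = 0.158), with Bmp7 at 2.17 ± 0.10. Of 79 oxidative phosphorylation subunits, 7 rose and 4 fell (4 and 2 adjusted over the list alone), with a median of -0.09, a mean of -0.02 and a camera direction above 0 (limma, adjusted p = 0.943). Without the dye swap of replicate 1, 16 of these subunits were called higher and 7 lower.

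The spike-in controls, 10 probes on 320 spots per array, had median log2 ratios of labelled Lgr5-GFP over labelled CD24hi channel of 0.69 and -0.02 on the first array and dye swap of replicate 1, and of 2.94 and 3.04 on those of replicate 2.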
